A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

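Chromatin bound by Fhl1 or Ifh1 was measured in budding yeast (Saccharomyces cerevisiae, W303 background) by chromatin immunoprecipitation followed by hybridisation to spotted arrays of intergenic regions (ChIP-chip). Per the labels' protocols, log-phase cultures in rich medium at 30 °C received rapamycin, an inhibitor of the TOR kinases, at 200 ng/mL or no drug, and were crosslinked for 30 min. Chromatin of a strain carrying a myc-tagged protein, and of the untagged wild-type strain as reference, was precipitated with an antibody against the myc epitope. Per the same protocols, the recovered DNA was amplified by ligation-mediated PCR, coupled to Cy3 or Cy5, hybridised together and read with a GenePix scanner. Whether the wild-type reference of the rapamycin arrays came from treated cells is not given in the sources used here.

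The deposited table held 6803 probes on 15 arrays as log2 ratios. The log base was read from the values: 2 to the power of each value was a ratio with 3 decimals for 100% of the values (tolerance 0.002 of the third decimal, multiplied by the ratio where it exceeds 1), against 1.12% for base e and 7.30% for base 10. Background correction, normalisation and spot filters of the authors are not given in the sources used here. The deposited log2 ratios were not centred. Their array medians were 0.13, 1.15 and -1.31 for Fhl1 untreated replicates 1 to 3. They were -0.34, 0.23, 1.24, -0.13 and -0.66 for Fhl1 rapamycin replicates 1 to 5. The medians were -0.88, -0.04, 1.11 and 1.74 for Ifh1 untreated replicates 1 to 4, and -0.16, 1.31 and -0.86 for Ifh1 rapamycin replicates 1 to 3. Values were missing at 1 probe of Ifh1 untreated replicate 1 and at 8 probes of Ifh1 untreated replicate 4. No 2 arrays held identical values. The direction of the ratio is unknown: the labels mention a dye swap in each condition without naming the array, and give neither the numerator nor whether swapped arrays were turned.

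Groups and replicate numbers came from the sample titles: Fhl1 untreated (3 arrays), Fhl1 rapamycin (5), Ifh1 untreated (4) and Ifh1 rapamycin (3). The labels call the replicates biological. The number of arrays limits the precision. Arrays may share a wild-type preparation, and testing a ratio against 0 would then leave out the spread between such preparations. Each array was centred on its median, with no loess or quantile step, because many probes of a ChIP array can shift one way. In limma 3.58.1 (R 4.3.3), lmFit and eBayes fitted 4 group means to all arrays, and probes with Benjamini-Hochberg adjusted p under 0.05 were called, two-sided. Every probe had values on at least 2 arrays of each group.

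A probe was assigned to the genes whose 5′ ends face it. The probe names give 1 neighbouring reading frame each. Which side of it the region lies on was worked out, after the data had been opened, from the probe names alone, by the presence of probes in gaps between genes: 38 of 41 genes with a gap only on the higher-coordinate side had a probe (92.7%), against 2 of 44 with a gap only on the other side (4.5%). Names and neighbours came from NCBI's table for the assembly R64, and 5307 of 5574 reading frames named by the array matched it. Of 5811 intergenic probes, 2840 lay upstream of 1 gene, 1513 of 2 genes and 1458 of none. No coordinates are given because the build behind the array is not given in the sources used here. A probe between 2 divergent genes is named with both, as RPL42B/CHS7.

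Before the data were examined, 15 gene lists, the tests and the rule for named genes were fixed. That a probe belongs to a list through the genes whose 5′ ends face it was decided after the files had been seen. The lists were cytosolic ribosomal protein (RP) genes of the large and of the small subunit, RP genes with an Abf1 site, mitochondrial RP genes, ribosome biogenesis, RNA polymerase I and III, translation factors, glycolysis, nitrogen catabolite genes, stress response, mating type, histones, regulators and strain loci, tRNA genes and snoRNA genes. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over lists within each contrast, and again with an estimated correlation. The rule names, for each enrichment, the 10 highest and 5 lowest called probes that lay on one side on every array of the group, and for each difference the 10 largest rises and falls among called probes whose arrays did not overlap. It always names the regulators and strain loci, the Abf1 list, RPL2B, RPL18B, RPL30, RPS6B, RPS11B, PGK1, TPI1 and TEF1, and the 3 members with the lowest p of each called list. Some genes that this rule names are not reported here. For each array, the RP level was the median centred log2 ratio of the 132 RP probes, and the RP AUC was the area under the ROC curve of these probes against all others. Both were compared with exact permutation tests of group means, over all splits of the arrays, with a two-sided p of 2 times the smaller tail (Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3).

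Because RP probes lay on opposite sides of the median on arrays of 1 group, 2 readouts were added after seeing the data. The first takes absolute values: the size of the RP level and the distance of the AUC from 0.5, which need no direction. The second turns each array's sign so that the median of the large-subunit RP probes is positive; such arrays are called aligned. On the 12 arrays outside Ifh1 rapamycin, the small-subunit probes, 4 of which are also in the large-subunit list, gave the same sign on each. On the 3 Ifh1 rapamycin arrays both lists lay within 0.17 of the median and took the same side on 2 arrays. Their signs were taken as not settled, so all 8 sign patterns were run. An aligned ratio above 1 is called enrichment with the tagged strain; this direction is likely, from the design alone, as the precipitated tag is absent from the reference. The level of the large-subunit list is then positive by construction. Arrays were also grouped into 4 clusters by average linkage on 6535 probes away from RP genes (mean r 0.18 within and -0.02 between clusters), and these clusters, each holding arrays of more than 1 group, were treated as technical batches.

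Alternatives were no centring, scaling to 1 spread, quantile normalisation, complete probes only, array weights, only the arrays compared, a sign rule based on correlations within a group, leaving out each array, a 2-fold limit, a replicate block, and for the list tests fry, ranks and single-gene probes. Added ones were the small-subunit list as the alignment key, a dye term, a cluster block, other sign patterns, membership by the probe's own name and, for the permutation tests, counting absolute differences. The fits were tested on simulated data with the real spread and 200 changed probes among 6803. For a change of 1 log2 unit, 4.1% were recovered for Fhl1 untreated, 48.7% for Fhl1 rapamycin, 26.3% for Ifh1 untreated and 6.3% for Ifh1 rapamycin enrichment, and 0.2% for the Fhl1 rapamycin effect. The shares were 0% for the Ifh1 rapamycin effect and the difference of the effects, and 0.3% and 0.1% for Ifh1 against Fhl1 untreated and with rapamycin. For 2 log2 units the shares were 93.1%, 98.5%, 97.3%, 93.7% and 73.6%, with 69.7% for the Ifh1 rapamycin effect, 18.3% for the difference of the effects, 72.1% for Ifh1 against Fhl1 untreated and 76.9% with rapamycin.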

Results

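The study asked where the forkhead-type factor Fhl1 and its partner Ifh1 sit on the yeast genome in growing cells, and what rapamycin changes. The data were 15 two-colour arrays, each setting chromatin precipitated from a tagged strain against chromatin of the untagged strain. There were 3 arrays of Fhl1 and 4 of Ifh1 from untreated cells, and 5 of Fhl1 and 3 of Ifh1 from cells given rapamycin at 200 ng/mL. Values are log2 ratios after centring each array on its median, as mean ± SD over arrays. On the arrays of Fhl1 and of untreated Ifh1, the promoters of cytosolic ribosomal protein (RP) genes stood apart from the rest of the genome. On the 3 Ifh1 rapamycin arrays their median shift was at most 0.10.

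The 132 probes upstream of RP genes, which encode the proteins of the ribosome, lay far from the array median on all 12 arrays outside Ifh1 rapamycin. The size of their median shift was 1.20 ± 0.41 for Fhl1 untreated (n = 3, a 2.30-fold ratio), 1.10 ± 0.31 for Fhl1 rapamycin (n = 5, 2.14-fold) and 0.88 ± 0.05 for Ifh1 untreated (n = 4, 1.84-fold). It was 0.04 ± 0.05 for Ifh1 rapamycin (n = 3, 1.03-fold). Among 10000 random lists of the same size, the shift exceeded 100% on each of the 12 arrays, and 11%, 38.9% and 97.2% on the Ifh1 rapamycin arrays. Regions only on the 3′ side of RP genes (121 probes) had a median of 0.12 over the 12 aligned arrays, against 1.00 for the RP promoters and -0.02 for all other probes.

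The side of the shift differed between arrays of the same group as deposited. RP promoters lay above the median on 1 of 3 Fhl1 untreated, 2 of 5 Fhl1 rapamycin and 2 of 4 Ifh1 untreated arrays, and below it on the others. The large- and small-subunit lists, which share 4 probes, took the same side on 12 of 12 of these arrays (exact binomial test, two-sided p = 0.000488). The fit planned on the values as deposited therefore averaged opposite signs: limma called 0 probes in each of the 9 results, with 205 to 429 probes at an unadjusted p under 0.05, and 0 of 135 list tests passed. The group means of the RP level as deposited differed by 0.03 between Fhl1 rapamycin and untreated arrays (exact permutation test, p = 0.929) and by -0.004 for Ifh1 (p = 0.971). Named genes are given below from the aligned arrays, on which the large-subunit RP list is positive by construction, a step chosen after seeing the data.

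**Figure D1:**
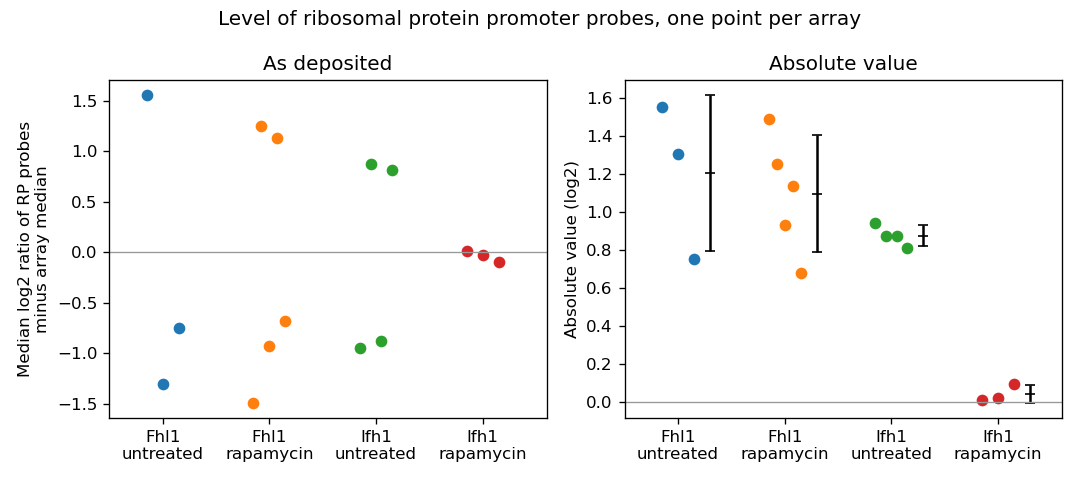
Median log2 ratio of the 132 RP promoter probes minus the array median, 1 point per array, as deposited (left) and as an absolute value (right, with mean and SD as bars). The absolute values range from 0.68 to 1.55 on the 12 arrays of Fhl1 and untreated Ifh1, and from 0.01 to 0.10 on the 3 Ifh1 rapamycin arrays.

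In untreated cells, Fhl1 enrichment centred on RP promoters. Of 45 probes called by limma, 43 were higher, and all 43 lay upstream of RP genes; 29 of the 79 large-subunit and 17 of the 57 small-subunit probes passed (52 and 36 when adjusted over the list alone). As lists, both were higher (camera adjusted p = 1.82e-75 and adjusted p = 3.85e-62, with an estimated correlation adjusted p = 0.000261 and adjusted p = 4.73e-05). The alignment had set the direction of the large-subunit list, which shares 4 probes with the small, so these tests do not test the direction. As deposited neither list was called (camera adjusted p = 0.282 and adjusted p = 0.169). Among the highest were RPS21B/LCB3 (2.56 ± 0.51, adjusted p = 0.000231) and TEM1/RPS1B (2.47 ± 0.72, adjusted p = 0.00115). RPL42B/CHS7 (2.46 ± 0.47), FRE8/RPS0B (2.45 ± 0.45), RPL12A (2.41 ± 1.03), RPL16A (2.29 ± 0.27), RPL13B/RPS16A (2.25 ± 0.05), YGR117C/RPS23A (2.25 ± 0.33) and RPS27B (2.22 ± 0.60) were also among them. RPL2B stood at 1.90 ± 0.25 (adjusted p = 0.00592), while RPS6B (1.74 ± 0.78, adjusted p = 0.0654), RPS11B (1.96 ± 0.69, adjusted p = 0.158) and RPL24A/RPL30 (1.38 ± 1.08, adjusted p = 0.655) did not pass. Both probes called lower lay outside the lists, upstream of YFR057W (-1.50 ± 0.41) and of COX5A, a cytochrome c oxidase subunit (-1.08 ± 0.37). Without replicate 1 the count was 11, and without replicate 2 it was 12. With only the 3 arrays in the fit it was 0.

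Fhl1 remained at RP promoters in cells given rapamycin. Of 66 called probes, 63 were higher and 62 of these lay upstream of RP genes, with 38 large-subunit and 27 small-subunit probes (59 and 43 adjusted over the list alone). Both lists were higher (camera adjusted p = 5.18e-72 and adjusted p = 1.61e-60, with an estimated correlation adjusted p = 0.000325 and adjusted p = 5.41e-05). This direction was again set by the alignment and not tested. RPL6A (2.40 ± 0.54, adjusted p = 0.00015), TEM1/RPS1B (2.30 ± 0.73), FRE8/RPS0B (2.29 ± 0.29), RPL16A (2.19 ± 0.48), RPL2A (2.16 ± 0.62) and RPL42B/CHS7 (2.15 ± 0.43, adjusted p = 1.69e-05) were among the highest (n = 5). YGR117C/RPS23A (2.14 ± 0.32), SOP4/RPS14B (2.11 ± 0.74) and RXT3/RPL31A (2.09 ± 0.56) followed. RPS6B (1.54 ± 0.76, adjusted p = 0.0152) and RPS11B (2.05 ± 0.70, adjusted p = 0.0132) passed here, and RPL24A/RPL30 did not (1.36 ± 1.17, adjusted p = 0.212). The single promoter outside the RP genes called higher, SLX9/TOM20, falls outside the naming rule and was chosen after its values were seen; it lay at 1.05 (SE 0.24, adjusted p = 0.0418). Lower probes lay upstream of YEA6, a mitochondrial carrier (-1.06 ± 0.31), YLR155C-B (-0.94 ± 0.38) and ASP3-4/YLR161W (-0.93 ± 0.32). Without replicate 1 the number called was 38.

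Between Fhl1 arrays with and without rapamycin no probe differed. limma called 0 probes, with 243 at an unadjusted p under 0.05, where the simulated fit recovered 73.6% of changes of 2 log2 units and 0.2% of changes of 1. Neither RP list was called (camera adjusted p = 0.231 for the large and 0.302 for the small subunit). The size of the RP level was lower by a mean of 0.11 with the drug, difference -0.11, within the spread between arrays (exact permutation test, p = 0.679). In the array clusters the difference was -0.30 (cluster 1), -0.38 (cluster 2) and 0.15 (cluster 3). Clusters 1 and 2 held 1 array of each condition, and cluster 3 held 1 untreated and 2 rapamycin arrays. Across RP probes the mean log2 ratios of the 2 conditions had r = 0.86 and rho = 0.87, where genes are not independent replicates. Of the probes called higher, 39 were shared, an overlap that the alignment on RP genes favours.

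Ifh1 in untreated cells occupied the same class of promoters. All 24 called probes were higher and lay upstream of RP genes, 16 of the large and 9 of the small subunit (55 and 32 adjusted over the list alone). Both lists were higher (camera adjusted p = 1.93e-57 and adjusted p = 2.14e-37, with an estimated correlation adjusted p = 0.000896 and adjusted p = 0.000554). Here too the alignment had set the direction. RPL42B/CHS7 was highest (2.15 ± 0.28, n = 4, adjusted p = 0.000208). RXT3/RPL31A (1.99 ± 0.84), RPS27B (1.90 ± 0.68), RPS24B (1.90 ± 0.42), RPL34B (1.90 ± 0.42), RPL35A (1.88 ± 1.21), RPL2A (1.83 ± 0.57), RPS19B (1.81 ± 0.58) and RPL20B (1.81 ± 0.30) followed. RPL16A (1.58 ± 0.19, adjusted p = 0.00412), RPL33B/IRC13 (1.61 ± 0.21) and RPL2B (1.57 ± 0.55, adjusted p = 0.0181) also passed. Leaving out an array left 14, 7, 10 or 6 calls (replicates 1 to 4), and with only the 4 arrays in the fit there were 0.

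In untreated cells, part of the promoters called for Fhl1 were also called for Ifh1. Of the 43 probes called higher with Fhl1 and the 24 with Ifh1, 19 were common. Independent lists would give 0.152, but the alignment of all arrays on RP genes favours overlap and the wild-type references may share material. The overlap was 0 without centring, 8 and 6 without Fhl1 replicates 1 and 2, and 8, 7, 9 and 5 without Ifh1 replicates 1 to 4. Across RP probes the means had r = 0.83 and rho = 0.83. limma called 0 probes that differed between the proteins (281 at an unadjusted p under 0.05). Both RP lists were lower with Ifh1 by camera, with median differences of -0.22 for the large subunit (adjusted p = 0.00603) and -0.31 for the small (adjusted p = 2.45e-05). These calls were lost with an estimated correlation (adjusted p = 0.645 and adjusted p = 0.162). Members with the lowest p were FRE8/RPS0B (0.96 ± 0.57 with Ifh1), TEM1/RPS1B (1.37 ± 0.52), YGR117C/RPS23A (1.27 ± 0.53), RPL36B (0.12 ± 0.53 against 1.39 ± 0.27 with Fhl1), SLX8/RPL23B (1.20 ± 0.65) and RPL21A (1.27 ± 0.51). None of these passed by itself. The sizes of the RP level differed by -0.33 (exact permutation test, p = 0.286, smallest possible 0.0571). They differed by -0.68 in cluster 1 (1 array of each protein) and by -0.46 in cluster 2 (1 Fhl1 and 2 Ifh1 arrays).

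On the Ifh1 rapamycin arrays no RP promoter was called. limma called 0 probes against 0 (358 at an unadjusted p under 0.05), and 0 under each of the 8 sign patterns. RPL16A lay at -0.17 ± 0.28, RPL2B at -0.46 ± 0.28, RPL33B/IRC13 at -0.01 ± 0.25 and RPL42B/CHS7 at 0.51 ± 0.25 (n = 3); the signs of these values depend on the alignment, which is not settled here. The mean size of the RP level differed by -0.83 between rapamycin and untreated arrays, with no overlap between the 4 and 3 arrays. This did not pass in an exact permutation test with the two-sided p taken as 2 times the smaller tail (p = 0.0571, the smallest this definition allows). Counting absolute differences, a definition added after seeing the data, the exact permutation p was 0.0286. The difference was -0.86 in cluster 1 (1 untreated array against 1) and -0.82 in cluster 2 (2 untreated arrays against 1). For the AUC, the distance from 0.5 was 0.32 ± 0.02 untreated and 0.03 ± 0.03 with the drug.

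Probe by probe, limma made 1 call for the Ifh1 rapamycin effect (411 probes at an unadjusted p under 0.05), where the simulated fit recovered 69.7% of changes of 2 log2 units and 0% of changes of 1. There was 1 call under 3 of the 8 sign patterns of the rapamycin arrays, and none with a cluster block, a replicate block or without Ifh1 untreated replicates 2, 3 or 4 or rapamycin replicates 1 or 2 (0 calls each). As lists, large-subunit promoters were lower with rapamycin (median change -0.86, camera adjusted p = 3.98e-28, with an estimated correlation adjusted p = 0.0152) and so were small-subunit promoters (median -0.81, adjusted p = 1.24e-20 and adjusted p = 0.00741). Adjusted over the list alone, 21 large-subunit and 11 small-subunit probes were lower and 0 higher. Here and in the comparisons of Ifh1 with Fhl1, arrays with an RP shift had been turned to make the large-subunit list positive. A fall then follows wherever the other group lacks a shift. The test of sizes, which needs no direction, could not pass with these arrays and so does not decide. Its exact permutation p was 0.0571 (adjusted 0.114), the smallest that its definition allows. Over the 8 sign patterns the median change of the RP probes ran from -0.97 to -0.82. Members with the lowest p were RPL16A, RPL2B and RPL42B/CHS7 in the large subunit, and RPS24B and RPS27B were among those of the small.

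Whether the drug changed Ifh1 more than Fhl1 was examined by the difference of the 2 effects. For the sizes, permuting the drug labels within each protein assumes no drug effect on either. Its p therefore does not test unequal effects alone. The change in the size of the RP level differed by -0.72 between the proteins (exact permutation of the drug labels within each protein, 1960 arrangements, p = 0.0786). For the AUC distance the difference was -0.28 (same exact permutation test, p = 0.0367). Over the 10 tests of sizes both adjusted p were above the threshold (0.131 and 0.114). Both RP lists were lower in the interaction by camera (medians -0.72 and -0.79, adjusted p = 2.83e-14 and adjusted p = 9.56e-11). With an estimated correlation neither held (adjusted p = 0.122 and adjusted p = 0.0804). limma called 0 single probes, with 297 at an unadjusted p under 0.05 (simulated recovery 18.3% for 2 log2 units and 0% for 1); RPL2B, RPL16A and RPL41A had the lowest p of the large subunit, and RPS7A (probe RKI1/RPS7A) and RPS17A (probe YML6/RPS17A) were among the lowest of the small.

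With rapamycin, Ifh1 lay below Fhl1 at 5 RP promoters, each with no overlap between the arrays. Among them, the values with Fhl1 and with Ifh1 were RPL16A (2.19 ± 0.48 to -0.17 ± 0.28, adjusted p = 0.00319), FRE8/RPS0B (2.29 ± 0.29 to -0.26 ± 0.72, adjusted p = 0.0092), YGR117C/RPS23A (2.14 ± 0.32 to -0.01 ± 0.23) and YML6/RPS17A (1.87 ± 0.33 to -0.48 ± 0.89, adjusted p = 0.0393). Across the 8 sign patterns 4 to 12 probes were called, each of them lower and upstream of an RP gene. Both RP lists were lower (medians -1.03 and -0.98, camera adjusted p = 9.03e-40 and adjusted p = 6.38e-37, with an estimated correlation adjusted p = 0.00416 and adjusted p = 0.000587). Sizes of the RP level differed by -1.05 (exact permutation test, p = 0.0357, the smallest possible, adjusted 0.114), and by -1.24, -0.91 and -0.81 in clusters 1, 2 and 3. Clusters 1 and 2 held 1 such array of each protein, and cluster 3 held 2 of Fhl1 and 1 of Ifh1. A replicate block over 3 shared numbers left 0 calls, and without Ifh1 rapamycin replicate 1 or 3 there were 2.

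**Figure D2:**
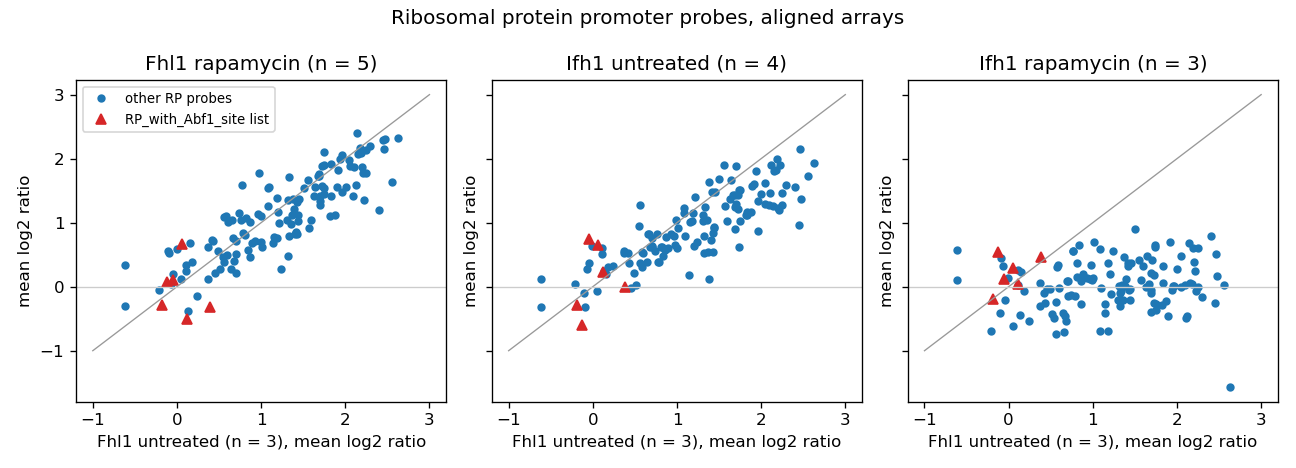
Mean aligned log2 ratio of each of the 132 RP promoter probes in Fhl1 untreated cells (x axis) against Fhl1 rapamycin, Ifh1 untreated and Ifh1 rapamycin (y axes), with the line of equality in grey and the Abf1 list as triangles. The correlation across probes is 0.86, 0.83 and 0.09, and the Abf1 list spans -0.18 to 0.39 on the x axis.

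As a list, RP genes with a site for the general factor Abf1 lay low among RP promoters. None of the 6 probes of this list was called in any result. Over the 12 aligned arrays their median was -0.07, against 1.09 for the 126 other RP probes (permutation test over probes with 100000 resamples, p = 4.0e-05; genes are not independent). The list lay below the other RP probes on 11 of 12 arrays, by a mean of -1.04 (SD 0.55, exact sign-flip test over arrays, p = 0.000977). This sets the list apart from the other RP probes only, since any list near 0 lies below them on arrays aligned in this way. In Fhl1 untreated cells RPS28B lay at -0.18 ± 0.45, RPL4A at -0.12 ± 2.07, RPL4B at 0.12 ± 0.35, YOR062C/RPL3 at -0.05 ± 0.15, RPS22B at 0.39 ± 0.59 and RPS28A/GLN4 at 0.06 ± 0.40. RPS28A/GLN4 was at 0.66 ± 0.76 with Fhl1 rapamycin and 0.64 ± 1.12 with Ifh1 untreated, and YOR062C/RPL3 at 0.75 ± 0.91 with Ifh1 untreated. RPL18B/TOS6, outside this list, lay at 0.05 ± 0.31 with Fhl1 untreated. Low values were not particular to the list. Over the 12 arrays RPP2B (-0.24), RPL1A (-0.12) and RPS14A (-0.06), also outside it, had means below 0. In all, 64 of the 132 RP probes were called higher in none of the 3 groups, where the simulated fits recovered 4.1% to 48.7% of changes of 1 log2 unit. With the 12 arrays pooled, a step chosen after the results were seen, 88 RP probes were called higher.

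Among the other lists, the promoters of glycolytic genes were higher as a list with Fhl1 in untreated cells (median 0.16, camera adjusted p = 0.017, with an estimated correlation adjusted p = 0.0397). With rapamycin the list was not called (median -0.06, adjusted p = 0.995), and the change between the conditions did not pass either (median -0.13, adjusted p = 0.135). No member passed by itself: ADP1/PGK1 lay at 0.76 ± 0.36, TDH3 at 0.77 ± 0.49 and CYC3/CDC19 at 0.77 ± 0.05, while TPI1 varied between arrays (0.32 ± 2.43). tRNA regions were higher with Ifh1 in untreated cells (median 0.13, adjusted p = 7.57e-05, with an estimated correlation adjusted p = 0.00818), again with 0 members called, and itT(AGU)O1 (1.18 ± 0.63) and itM(CAU)J2 (0.86 ± 0.55) were among those with the lowest p. They were higher with Ifh1 than with Fhl1 (adjusted p = 0.0447), a call lost with an estimated correlation (adjusted p = 0.162); itM(CAU)O2, itT(UGU)P and itW(CCA)G2 had the lowest p.

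The remaining lists were not called in any of the 9 results. Their smallest camera adjusted p were 0.264 for RNA polymerase I and III, 0.599 for the Abf1 list, 0.721 for histones, 0.340 for mating type, 0.134 for mitochondrial RP genes and 0.231 for nitrogen catabolite genes. They were 0.261 for regulators and strain loci, 0.382 for ribosome biogenesis, 0.476 for snoRNA genes, 0.406 for stress response and 0.372 for translation factors. At TEF1, the gene of elongation factor 1A, Fhl1 rapamycin lay at 0.79 ± 0.62 and Ifh1 untreated at 0.90 ± 0.56 without passing (adjusted p = 0.282 and adjusted p = 0.313).

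Neither protein was called at its own promoter or at any other regulator of the list. FHL1 lay at -0.09 ± 0.65 with Fhl1 untreated and 0.22 ± 0.10 with Ifh1 untreated, and IFH1/UCC1 at 0.06 ± 0.22 and 0.11 ± 0.56. CRF1, the corepressor gene, varied widely (-0.14 ± 2.08 and -0.45 ± 1.69). SFP1 (0.30 ± 0.14), ARG82/HMO1 (0.09 ± 0.59), RAP1 (0.27 ± 0.76), RAD27/ABF1 (0.20 ± 0.53), PUS7/ESA1 (0.08 ± 0.33) and GCN4/YEL008W (0.78 ± 0.48) did not pass with Fhl1 untreated. For the TOR pathway, ARP3/TOR1 lay at -0.12 ± 0.38, TOR2 at 0.11 ± 0.48, TAP42 at 0.30 ± 0.98, SCH9 at 0.71 ± 0.41 and the probes of STP4/SIT4 at 0.33 ± 0.96 and -0.42 ± 0.83. The marker loci TRP1 (probe SOK1/TRP1, 0.13 ± 0.79), HIS3 (probe MRM1/HIS3, 0.07 ± 0.32), URA3 (-0.57 ± 0.48), ADE2 (-0.14 ± 0.67) and CAN1/NPR2 (-0.30 ± 0.66) did not pass either. Of this list, LEU2 had no upstream probe.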

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

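Except for the spread of the Abf1-list probes, the tests of explanations in this part, including the counts over other splits, were chosen only after the results were seen.

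Among the genes named in the report, 10 of 150 groups of 4 or 5 arrays held 1 array far from the others by Dixon's ratio, where chance gives about 1 in 20. In Fhl1 rapamycin these were RPS21B/LCB3 in replicate 3 (1.34, lowest), RPL12A in replicate 5 (-0.52, lowest), CAN1/NPR2 in replicate 1 (-1.67, lowest) and RPS22B in replicate 4 (-1.73, lowest). In Ifh1 untreated they were TEM1/RPS1B in replicate 3 (0.61, lowest), RPL34B in replicate 1 (2.52, highest), SCH9 in replicate 2 (1.81, highest), ARP3/TOR1 in replicate 1 (0.57, highest), IFH1/UCC1 in replicate 4 (-0.72, lowest) and RPL18B/TOS6 in replicate 4 (-1.71, lowest). The values are aligned log2 ratios.

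The effect of rapamycin on the RP promoters differed between the proteins by the AUC distance, by -0.28 (exact permutation test, two-sided p = 0.0367), before adjustment over the 10 tests of sizes. The permutation assumes no drug effect on either protein, so this p does not test unequal effects alone. For single probes the interaction gave 0 calls by limma (297 at an unadjusted p under 0.05), a count that each of 100 drawn splits reaches whatever the data (highest other 1). As deposited the count was 0 as well (232 at an unadjusted p under 0.05), reached by 100 of 100 splits (highest other 6).

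The small RP shift on the Ifh1 rapamycin arrays, which in replicate 3 still exceeded 97.2% of random lists, was weighed against technical causes. Noise that hides a shift is argued against: the size of the shift plus the 95th percentile of random lists was at most 0.184 on these arrays, against at least 0.682 for the shift on the other arrays. Their median absolute deviations were 0.766, 0.518 and 0.428, of which replicate 1 lay above the largest of the other arrays (0.747). A batch that follows the array clusters is argued against too. Each Ifh1 rapamycin array lay at least 0.58 below the weakest other array of its own cluster, where the SD of the sizes over the 12 other arrays was 0.29. The clusters rest on weak correlations (mean r 0.18 within) and on no label. A batch shared by the Ifh1 rapamycin arrays alone was therefore not tested. Poor precipitation of tagged Ifh1 from treated cells remains open, because limma called 0 probes on these arrays (358 at an unadjusted p under 0.05) and none could serve as a positive control. A loss of Ifh1 from RP promoters in treated cells, named by the design, may explain the pattern. It cannot be told apart here from poor precipitation or from a batch of these arrays alone.

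The opposite signs of the RP promoters within a group were weighed next. A fixed dye bias of these probes is argued against: it would show on the Ifh1 rapamycin arrays, where the largest size was 0.0975 against at least 0.682 on the other arrays. An inverted ratio on some arrays has the value it needs: the small-subunit probes had a mean r of -0.449 between arrays of opposite sign and 0.549 between arrays of the same sign. These probes did not set the signs, except for 4 that are also in the large-subunit list and were not left out. A single unturned dye swap in each group is argued against as the whole account, since 2 of the 3 groups had more than 1 array on the minority side. No biological explanation was tested.

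The missing signal at RP promoters of the Abf1 list was weighed last. A wrong flank is argued against: the 5 probes on the 3′ side of these genes had a median of 0.0460, against 1.09 at the other RP promoters. Weak spots have the value they need, by a narrow margin, and stay open. The SD over the 12 arrays was 0.73 at the median of the list. That lay above the 75th percentile of the other RP probes (0.713), the limit set beforehand for weak spots, and above their median (0.605). A different set of factors at these promoters may also explain it and was not tested.

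The counts of called probes were compared with those of other splits of the same arrays. For Ifh1 against Fhl1 with rapamycin, aligned, the real split gave 5 calls. Of 56 splits, 1 gave as many, itself, with 0 at most among the others. Chance is not excluded by this, as it was 1 of several split comparisons, chosen after the results were seen. Mixed splits also put arrays with and without an RP shift into 1 group, which widens the spread and makes calls unlikely. In the exact permutation test of sizes the same contrast had an adjusted p of 0.114. The count of 5 fell to 0 with a replicate block and to 2 without Ifh1 rapamycin replicate 1 or 3. For the aligned Ifh1 rapamycin effect the real count was 1, and 2 of 35 splits gave as many (highest other 1), so chance could not be excluded. A real count of 0 is reached by any split, so these counts say nothing about chance: 56 of 56 for the aligned Fhl1 rapamycin effect (243 at an unadjusted p under 0.05 by limma, highest other 1) and 35 of 35 for Ifh1 against Fhl1 untreated (281, highest other 0). As deposited, with 0 calls by limma each, these were 56 of 56 for the Fhl1 rapamycin effect (217 at an unadjusted p under 0.05), 35 of 35 for the Ifh1 rapamycin effect (218, highest other 1), 35 of 35 for Ifh1 against Fhl1 untreated (243, highest other 1) and 56 of 56 with rapamycin (205, highest other 1). For the Fhl1 rapamycin effect as deposited another split gave 66 calls. As deposited, 3 of the 8 Fhl1 arrays had a positive RP level and 5 a negative one, a division of the same sizes. Whether this division was the split with 66 calls is not shown here.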

How the results depend on the processing

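Of 595 alternatives, 249 were planned and 346, including every alternative to the aligned counts and to the sizes, were chosen after seeing the data. As deposited, all 163 alternatives of the fits across probes and lists gave 0 calls (limma; 205 to 429 probes at an unadjusted p under 0.05 in the fits as reported). The aligned enrichment counts of Fhl1 untreated (45), Fhl1 rapamycin (66) and Ifh1 untreated (24) stayed within 37 to 48, 51 to 71 and 22 to 30 under scaling, quantile normalisation, array weights, the small-subunit key, a dye term, a cluster block and a 2-fold limit. Without centring each was 0, as was the shared untreated count (19), with array medians from -1.31 to 1.74 left in the values. With only the arrays compared, Fhl1 untreated and Ifh1 untreated gave 0 (fewer arrays). Leave-one-out counts were 11 to 48 for Fhl1 untreated (11 without replicate 1, 12 without replicate 2), 38 to 69 for Fhl1 rapamycin (38 without replicate 1) and 6 to 14 for Ifh1 untreated (14, 7, 10 and 6 without replicates 1 to 4). For the shared count they were 5 to 25 (8 and 6 without Fhl1 replicates 1 and 2; 8, 7, 9 and 5 without Ifh1 replicates 1 to 4). The 1 call of the Ifh1 rapamycin effect became 2 with array weights and 0 without centring, with the small-subunit key, a cluster block, only the arrays compared, a replicate block or the sign pattern with the fewest calls; leave-one-out gave 0 to 1 (0 without Ifh1 untreated replicate 2, 3 or 4 or rapamycin replicate 1 or 2). The 5 calls of Ifh1 against Fhl1 with rapamycin became 1 without centring, 18 with array weights, 8 with the small-subunit key, 3 with a cluster block, 0 with a replicate block and 12 with the sign pattern with the most calls; leave-one-out gave 2 to 5 (2 without Ifh1 rapamycin replicate 1 or 3). The RP level as deposited changed sign for Fhl1 with a replicate block (-0.22), for Ifh1 with scaling (0.11) and a replicate block (0.28), and for their difference likewise (0.10 and 0.50). The AUC did so with a replicate block for Ifh1 (0.101) and the difference (0.0934). Leave-one-out levels ran from -0.54 to 0.89, -0.31 to 0.30 and -0.89 to 0.54 (Fhl1, Ifh1, difference), and AUCs from -0.0893 to 0.293, -0.114 to 0.103 and -0.299 to 0.0832; none of these passed in an exact permutation test under any setting. The size of the RP level for Fhl1 turned to 0.0124 with own-name probes and 0.0190 with a replicate block (leave-one-out -0.332 to 0.0672, positive only without untreated replicate 1). The difference of sizes passed with own-name probes (-0.44, exact permutation p = 0.0276) and without Fhl1 untreated replicate 1 or rapamycin replicate 5 (leave-one-out -0.90 to -0.50). Counting absolute differences, the Ifh1 sizes passed (-0.83 and, for the AUC, -0.298, exact permutation p = 0.0286 for both), by the definition of the tail. Ifh1 against Fhl1 with rapamycin no longer passed with a replicate block (-1.18 and, for the AUC, -0.324) or leave-one-out (-1.16 to -0.95, and -0.331 to -0.301), where fewer arrays raise the smallest possible p. The AUC difference no longer passed with a replicate block (-0.298) or without any 1 of the Ifh1 arrays (leave-one-out -0.298 to -0.256). The cause of the other changes was not tested. The labels do not say whether arrays of the same replicate number are paired within each protein. Untreated and rapamycin arrays of numbers 1 to 3 fell in clusters 1 and 4, 2 and 1, and 3 and 2 for Fhl1. For Ifh1 they fell in clusters 4 and 1, 1 and 2, and 2 and 3. This argues against a batch shared by number, as far as the clusters, which rest on weak correlations, mark batches. A replicate block may then join arrays of different batches. As deposited, the correlation across probes between the deviations from the group means of arrays with the same number was -0.229 to 0.0963. Some of these pairs had opposite RP signs, and an inverted array would turn the sign of such a correlation. Between the proteins, rapamycin arrays of the same number had r of 0.062, 0.115 and -0.077 across probes outside the RP lists. Signal over background could not be computed, since spot intensities were not used here.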

Other observations

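The tests in this part, and the pooling of arrays, were chosen only after the results were seen.

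With the 12 aligned arrays of Fhl1 and untreated Ifh1 pooled, limma called 98 probes higher, 88 of them upstream of RP genes, and 5 lower. Of the 132 RP probes, 79 (59.8%) lay above 0 on all 12 arrays, against 4 of 6671 others (0.06%). The alignment, which made the large-subunit RP list positive on each array, favours RP probes in both counts. In all, 10 of the others lay on one side on all 12 arrays, where chance gives 0.0488% for both sides together. These 4 were chosen after their values were seen: TDH3, a glycolytic dehydrogenase gene (0.86, SE 0.16, adjusted p = 0.00356), TEF1 (0.77, adjusted p = 0.013), ERG9, of sterol synthesis (0.40), and the probe of the reading frame YOR235W beside RPL33B (1.17, adjusted p = 0.000215). Below 0 on all 12 lay 6 probes, among them the one upstream of MDS3 (-0.58).

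As a hypothesis, tRNA regions lie on the side of the RP promoters because their flanking genes are strongly transcribed, which may raise any precipitate. A rise of equal size in the untagged reference would cancel in the ratio. The 292 tRNA regions were 250 probes beside tRNA genes and 42 of the tRNA genes themselves. These regions lay above 0 on 11 of 12 aligned arrays (mean 0.10 ± 0.09, exact sign-flip test, two-sided p = 0.000977), with means of 0.07 on Fhl1 and 0.18 on untreated Ifh1 arrays. They also lay above 0 on the 3 Ifh1 rapamycin arrays as aligned (0.04, 0.06 and 0.09), whose signs are not settled. The glycolysis list, as the test of strong transcription, had a mean of 0.0869 over the 12 arrays and lay above 0 on 7 (exact sign-flip test, two-sided p = 0.189), which leaves the hypothesis undecided.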
